A study of Mus musculus with 2 samples.

How the data were processed

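Xenium data of 2 mouse skin sections, 1 WT and 1 Utx-cKO, were analysed from the cell tables and transcript tables. Per the labels, 5 µm sections of fixed, paraffin-embedded skin were probed with a custom 480-gene panel and negative control probes. The deposited cell tables give counts of decoded transcripts per segmented cell, with cell positions and areas. The deposited transcript tables list each decoded transcript with its gene, position, cell and a quality score of at most 40. The counts in the deposited cell tables equal the number of gene transcripts with a score of at least 20 in each cell, checked in all 40371 and 52308 cells. The software and version behind decoding and segmentation are not given in the sources used here. Nucleus outlines were not used here, since nucleus areas stand in the cell tables.

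Gene transcripts with a score of at least 20 inside cells were counted per cell and gene. Cells with at least 20 transcripts were kept, 33263 in WT and 37395 in Utx-cKO. No doublet caller was run. Of 20 negative control probes, 2 stood far above the rest. The median probe had 5 counts in WT cells and 9.5 in Utx-cKO cells, and the highest 117 and 199. 9 and 14 genes did not exceed that highest probe. Each gene named as higher or lower exceeds it in both sections when counted over all cells. Within the smaller sets compared, some named genes had fewer counts than that.

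Counts were scaled to the median per cell and log-transformed, with no integration of sections. 30 principal components, 15 nearest neighbours and Leiden clustering (resolution 1, fixed seed) gave 20 clusters. A cluster was called epithelial where markers of basal, suprabasal, granular and upper follicle keratinocytes made up at least 6% of its counts. The lowest epithelial cluster had 7.06% and the highest other 4.63%. A class name needs at least 3 of its markers among the cluster's 10 leading genes, more than for any other class. Leading genes are those of highest fold over other cells, detected in at least 5% of the cluster's cells. These naming rules were chosen after the data were seen. They named 4 epithelial clusters, and the others are called by number or leading genes. The marker lists, 18 gene lists, size rules and most alternatives were fixed before the data were examined.

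With 1 section per group no test was run. Counts were summed over the cells of a set, scaled to the same panel total (CPM), and compared as log2 ratios of Utx-cKO over WT. Genes needed at least 200 counts over both sections, or 100 within a class, and a ratio of at least 1.5 either way is a rule of size. Intervals are exact 95% intervals for counting error: Poisson for levels, conditional binomial for ratios and Clopper-Pearson for shares. They leave out differences between animals. List medians were placed among 10000 random lists of the same size, matched in 5 bins of expression. That percentile describes these 2 sections and is no test.

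Genes named for epithelial cells are the 12 highest and 12 lowest ratios past 1.5-fold with the same direction in all pairings of the left and right sides of the sections. The 5 highest and 5 lowest are named for non-epithelial cells and whole sections, and the 4 highest and 4 lowest for each named class, leaving out its markers and leading genes. Kdm6a is always named. Some values that met these rules are not reported here. Members of lists and markers with the largest ratios are named beside them.

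Strips are connected areas of tissue with at least 1000 cells, 4 in each section, found after the data were seen. They are not replicates. If strips were exchangeable, 2.86% of genes would have all strips of one section on one side of the other's. Tissue length is measured along each strip in steps of 100 µm. Distances were taken from granular keratinocyte-like cells, because no cluster on all genes was named suprabasal. Shares of classes come from a clustering without the 69 genes at least 1.5 times apart in epithelial cells. Of 2451 cells called sebocyte-like on all genes, 2197 (89.6%) were also called so without these genes, where the class held 3688 cells.

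Alternatives were scores of at least 30, transcripts over nuclei alone, cell minimums of 10 and 40 transcripts, a gene minimum of 50 counts and mean counts per cell. Others were ratios centred on the median, totals without the 10 most abundant genes, 1 side of the section at a time, and cells thinned to 20 transcripts. Clustering was varied with resolutions of 0.5 and 2, without differing genes, at equal cluster shares and with cells called epithelial by their own markers. Leaving out each strip, and shares from clustering on all genes, were added after the data were seen.

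The comparison of counts was tested on simulated data, drawn from the levels pooled over sections at the depth of each. The simulation held counting error only, with no variation between strips or animals. It therefore cannot show how often such variation alone passes the size rule. In the epithelial simulation, with 435 genes, all of 92 genes changed 2-fold were found past the size rule, 94.4% of 89 genes changed 1.8-fold, and 0% of 254 unchanged genes. Intervals covered the true ratio for 94.5% of genes. Of 200 random lists without effect, 5% fell outside the central range of percentiles, 2.5 to 97.5. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.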

Results

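Whole skin of female B6/129 mice was profiled by Xenium, an imaging assay that decodes single RNA molecules in place in a tissue section. The panel held 480 genes. There were 2 sections, 1 from a WT control and 1 from a Utx-cKO mouse line in which Krt14-Cre removes Kdm6a (Utx), a histone demethylase, from keratin-14 expressing tissues. The comparison asks which differentiation and lineage genes of the skin epithelium differ without Kdm6a. With 1 section per group there are no replicates. No difference was therefore tested, and every interval given is an exact 95% interval for counting error only. Each section held 4 separate strips of tissue, whose animals and skin sites are not given in the sources used here. Comparisons of strips, within or between sections, are description and no test.

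The WT section held 40371 segmented cells and 3540184 gene transcripts of sufficient quality, of which 74.7% lay in cells. The Utx-cKO section held 52308 cells and 2875112 transcripts, of which 84.9% lay in cells. Cells with at least 20 transcripts numbered 33263 and 37395, with medians of 62 and 48 transcripts per cell. Clustering gave 20 clusters, 9 of them epithelial by keratinocyte markers, with 14570 WT and 18742 Utx-cKO cells.

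Kdm6a transcripts remained abundant in epithelial cells of the Utx-cKO section. The level was 2782 CPM (counts scaled to the same panel total; 2689 to 2876) in WT and 2227 CPM (2148 to 2309) in Utx-cKO, a log2 ratio of -0.32 (-0.39 to -0.25). Non-epithelial cells had 2762 and 2597 CPM, a log2 ratio of -0.09. Among epithelial clusters, the log2 ratio was 0.05 (-0.07 to 0.17) in basal keratinocyte-like and 0.08 (-0.10 to 0.26) in granular keratinocyte-like cells. It was -0.58 (-0.78 to -0.39) in upper hair follicle-like and -0.71 (-0.99 to -0.42) in sebocyte-like cells, and between -0.33 and -0.86 in the 5 unnamed epithelial clusters. The unnamed cluster led by the melanocyte markers Dct and Pmel, called epithelial by its keratinocyte markers, had -0.58. Background can be read from the Y-linked genes Uty and Kdm5d, chosen after their values were seen: they had 50 and 43 counts in the WT section and 57 and 49 in the Utx-cKO section, against 7118 and 5433 for Kdm6a. Epithelial strips ranged from 1723 to 3504 CPM in WT and from 1797 to 2711 CPM in Utx-cKO. The pooled ratio rests partly on single strips: it was -0.07 without WT strip 3 and -0.53 without Utx-cKO strip 3. In each epithelial cluster the strips overlapped, and WT strip 3 was the highest WT strip. Sebocyte-like WT strips had 1242, 1323, 3245 and 1305 CPM, against 1296 CPM over all Utx-cKO cells of that class. Upper hair follicle-like WT strips had 2470, 2298, 4336 and 2584 CPM, against 2135 CPM. The lower ratios of these clusters thus rest partly on that strip too. Whether the probes lie in the deleted part of the gene is not given in the sources used here.

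**Figure D1:**
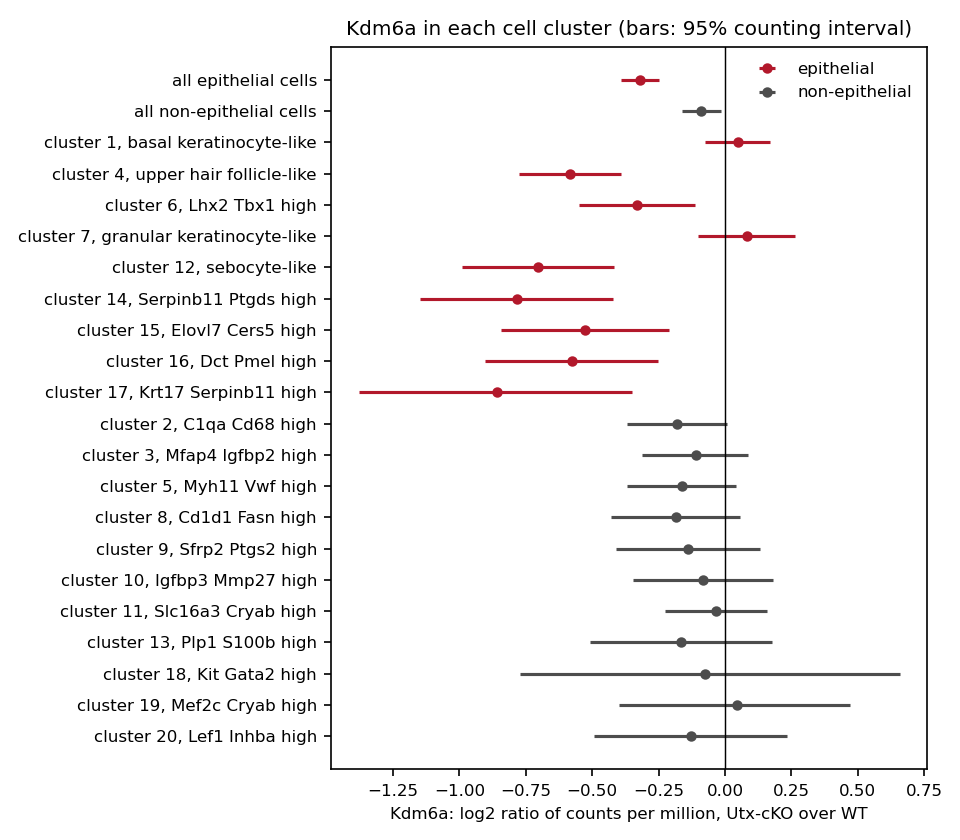
Log2 ratio of Kdm6a CPM, Utx-cKO over WT, in all epithelial and non-epithelial cells and in each of the 20 clusters, where points are ratios and bars are 95% counting intervals. The ratio is 0.05 in basal keratinocyte-like cells and -0.71 in sebocyte-like cells, where WT strip 3 lay far above the other WT strips.

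Genes with higher counts in epithelial cells of the Utx-cKO section included Akr1c18, Gsdmc, Rgs4, Elovl6, Cidea and 4 Sprr genes. Akr1c18, which encodes a steroid dehydrogenase, was 4.18 times higher (log2 ratio 2.06, 1.99 to 2.13), at 7028 against 1682 CPM. Gsdmc, a member of the pore-forming gasdermin family, was 3.92 times higher (1.97, 1.78 to 2.16), and Rgs4, a regulator of G protein signalling, 3.85 times (1.94, 1.74 to 2.15). The fatty acid elongase Elovl6 was 2.45 times higher (1.29, 1.25 to 1.33) and Cidea, a lipid droplet protein, 2.39 times (1.26, 1.19 to 1.32). Sprr2a2, Sprr2a3, Sprr1b and Sprr2a1, precursors of the cornified envelope, were higher too (1.32, 1.28, 1.18 and 1.09), while Sprr2h (0.56) and Sprr1a (0.46) stayed under 1.5-fold. Elf3, an epithelial transcription factor, was 2.74 times higher and Cd274, which encodes PD-L1, 2.10 times. For Rgs4, Elovl6, Cidea and Cd274 each Utx-cKO strip lay above each WT strip. For the other genes the strips overlapped.

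Genes with lower counts in the Utx-cKO epithelium included Ptgds, Fgf1, Cd3g, Cd3e and Igfbp3. Ptgds, a prostaglandin D synthase, was 2.25 times lower (log2 ratio -1.17, -1.41 to -0.94) and the growth factor Fgf1 2.02 times lower (-1.02, -1.16 to -0.87). The T cell receptor subunits Cd3g and Cd3e were 2.00 times (interval -1.18 to -0.82) and 1.82 times lower (interval -1.01 to -0.72), and Prf1, the perforin of cytotoxic cells, 1.66 times. Igfbp3 was 1.99 times lower, the receptor kinase Axl 1.63 times, the epidermal lipoxygenase Aloxe3 1.61 times, Them5 1.56 times, and Irf4 and the cornified-layer gene Hrnr each 1.55 times. In Ptgds, Fgf1, Cd3g, Cd3e, Axl and Aloxe3 each Utx-cKO strip lay below each WT strip. The lowest ratio, that of the transglutaminase Tgm3 (-1.55, -1.76 to -1.34), came from 1 strip: without WT strip 3 it was 0.64. Without that strip Aloxe3 (-0.27), Hrnr (-0.24), Them5 (-0.49) and Prf1 (-0.58) were under 1.5-fold too, as was Irf4 without WT strip 1 (-0.34).

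**Figure D2:**
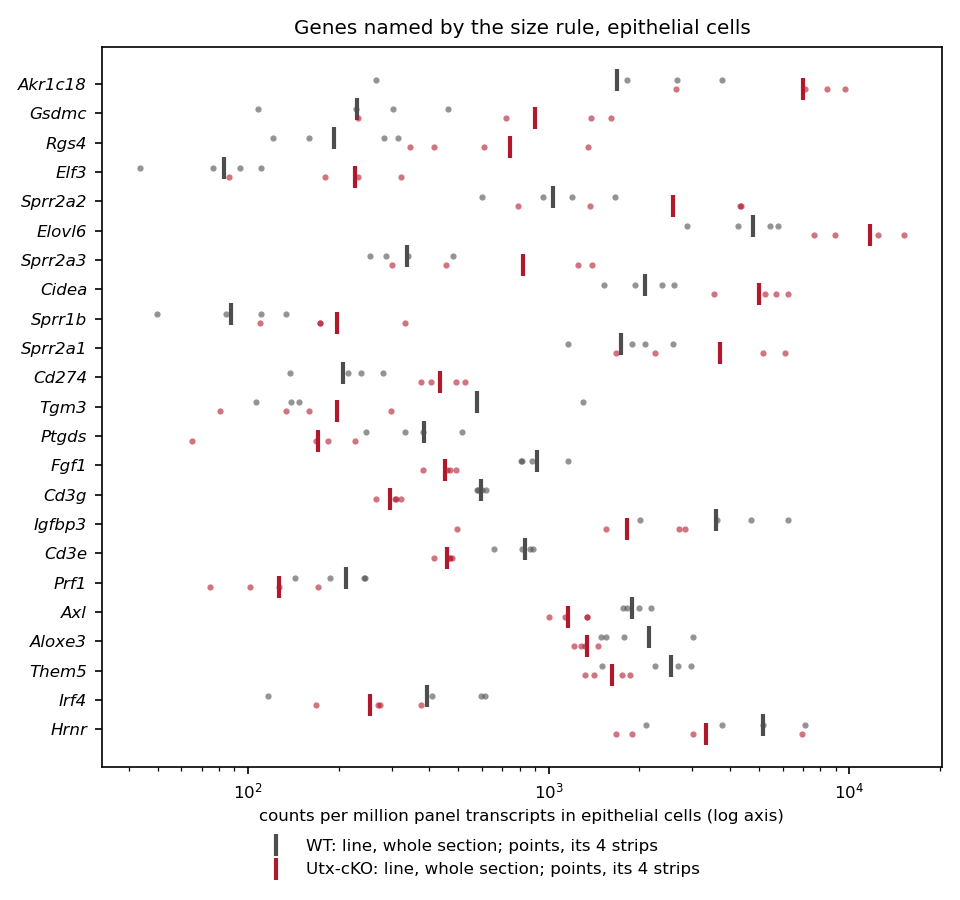
CPM in epithelial cells (log axis) for genes named by the size rule, with vertical marks for whole sections and points for the 4 strips of each. Strips of the sections are apart for Elovl6 and Cd3g and overlap for Akr1c18 and Tgm3.

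In all, 55 of 439 genes compared in epithelial cells were at least 1.5 times higher in the Utx-cKO section and 14 at least 1.5 times lower. This balance depends on the scale. It was 41 and 30 with ratios centred on their median (0.12), 25 and 53 with mean counts per cell, and 46 and 20 with the 10 most abundant genes left out of the total. Lower genes also numbered 22 without WT strip 1 and 33 without Utx-cKO strip 3. Mean counts per epithelial cell were 84.5 in WT and 71.1 in Utx-cKO. In cells of all kinds, negative control probes had 331 transcripts beside 2645045 gene transcripts in WT, and 561 beside 2442196 in Utx-cKO. Background was thus higher in Utx-cKO on the CPM scale, and its part in the number of higher genes was not tested. All 4 Utx-cKO strips lay above all WT strips for 16 genes and below them for 17, together 7.52% of genes, where exchangeable strips would give 2.86%. Single settings moved some named genes by more than 1.5 times or to under 1.5-fold. Akr1c18 had a log2 ratio of 1.46 without WT strip 3. With each cluster at the same share in both sections, Akr1c18 had 1.43, Elovl6 0.56, Cidea 0.55, Axl -0.56, Igfbp3 -0.57 and Irf4 -0.31. With epithelial cells called 1 by 1 from their markers, Rgs4 had 1.18 and Igfbp3 -0.32.

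Of the gene lists fixed before the data were examined, sebaceous gland and lipid synthesis stood highest. Of its 10 measured members, 7 were at least 1.5 times higher and 0 lower, led by Elovl6, Cidea and Elovl3 (log2 ratio 0.92). The median log2 ratio of 0.83 was at percentile 100.0 of 10000 random lists matched on expression, and the list's Utx-cKO strips lay above the WT strips for 4 members. With each cluster at equal shares the list's median was 0.20. Within sebocyte-like cells it was 0.04 over 5 members, with the cluster's leading genes left out. Elovl6, Cidea and Elovl3 are among these leading genes, so that median does not cover them. Of the leading genes, only Akr1c18 and Cyp1a1 were at least 1.5 times apart within sebocyte-like cells. Upper hair follicle genes had 3 of 6 members higher and 0 lower (median 0.53, percentile 99.4), among them Krt79 (0.82) and Krt17 (0.60). Krt79 also stands in the lipid list. Wound and stress keratins and alarmins had 4 of 8 members higher and 0 lower (median 0.58, percentile 97.9), namely Sprr1b (1.18), the keratins Krt16 (1.00) and Krt17, and Sprr2d (0.71). Interferon and chemokine genes had 3 of 7 higher and 0 lower (median 0.53, percentile 98.6). Among them were Ccl20, a chemokine for Ccr6-bearing cells (0.95), and Il17a (0.73).

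Granular and cornified layer genes split. Of 17 measured, 2 were higher (Sprr1b and Sprr2a1) and 3 lower (Tgm3, Aloxe3 and Hrnr), with a median of -0.26 at percentile 0.34. That median was 0.03 without WT strip 3 and 0.07 with cells called by their markers. Basal epidermis genes had 0 of 9 members at least 1.5 times apart (median -0.26, percentile 5.22), with Dst (-0.56), which encodes an anchor of hemidesmosomes, and Krt15 (-0.49) lowest. Utx-cKO strips lay below WT strips for 4 of the 9. With each cluster at equal shares the list's median was -0.026. Suprabasal differentiation genes had 0 of 12 (median -0.05, percentile 40.6), with Krt1 at 0.46 and Klf4 at -0.40.

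The remaining lists held few members past 1.5-fold in epithelial cells. Retinoid genes had 2 of 6 higher, among them Aldh1a3 (0.69), with a median of 0.20 (percentile 81.3). Outer root sheath genes had 1 of 2 higher, Krt17 (median 0.15, percentile 65.8). Collagen and matrix genes had 1 of 7 lower, Lum at -0.62 (median -0.15, percentile 17.6). None was past 1.5-fold among 7 cell cycle genes (median 0.12, percentile 73.7), 8 chromatin regulators (-0.04, 47.4) and 5 Wnt genes (0.05, 38.1). The same held for 4 hair follicle stem cell genes (-0.15, 25.8) and 3 hair matrix genes (-0.03, 37.2). It also held for 3 Hedgehog, BMP and TGF-beta genes (0.30, 84.7) and 2 immediate early genes (0.35, 88.9), whose median was -0.043 without Utx-cKO strip 1. Within the chromatin list, Kmt2a had a log2 ratio of -0.26 and the paralogue Kdm6b 0.21. The hair shaft list had 0 of its genes on the panel.

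**Figure D3:**
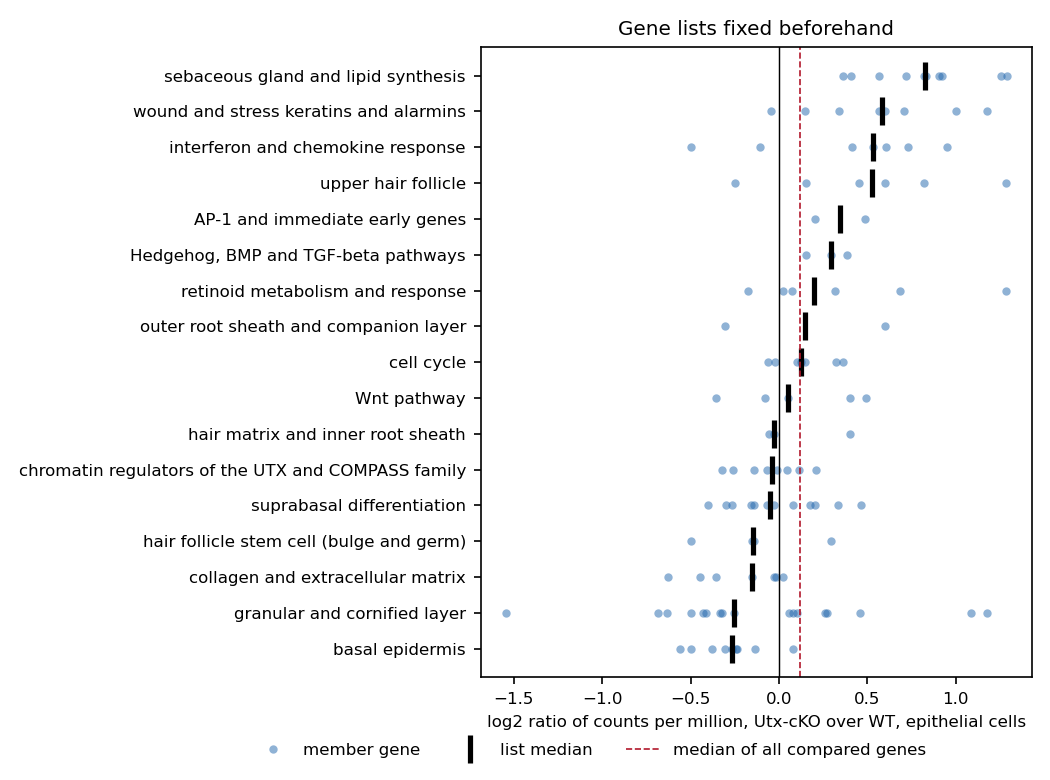
Log2 ratio of CPM, Utx-cKO over WT, in epithelial cells for each measured member (points) of each gene list, with list medians as vertical marks and the median of all compared genes (0.12) as a dashed line. Medians run from -0.26 for basal epidermis to 0.83 for sebaceous gland and lipid synthesis.

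Markers of other cell types, as they were counted in epithelial cells, differed by type. T and NK markers had 0 of 5 higher and 2 lower (median -0.23, percentile 6.18): beside Cd3g and Cd3e, Cd3d had -0.23, Thy1 -0.12 and Cd8a 0.52. Fibroblast markers had 1 of 2 lower (median -0.44, percentile 4.68), endothelial markers 1 of 4 higher, Flt1 (median 0.42, percentile 60.0), and mast cell markers 1 of 3 higher, Gata2 (median 0.53, percentile 80.3). No member was past 1.5-fold among the 2 macrophage (median 0.13), 2 dendritic (0.39), 5 melanocyte (-0.10) and 4 pericyte markers (0.12). The same was true of the 2 lymphatic endothelial (0.25), 2 Schwann cell (-0.05), 1 neutrophil (0.22) and 1 dermal papilla marker (0.15). Skeletal muscle, adipocyte and B cell markers had 0 measured members.

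With each cell thinned to 20 transcripts, 2.99% (2.72 to 3.27) of WT and 1.85% (1.66 to 2.05) of Utx-cKO epithelial cells held a Cd3d, Cd3e or Cd3g transcript (exact Clopper-Pearson intervals). Their strips ranged from 2.69% to 3.35% and from 1.67% to 2.11%. Before thinning the shares were 7.11% and 4.51%, at median depths of 70 and 57 transcripts. Among thinned basal keratinocyte-like cells the shares were 5.35% and 2.99%, among granular keratinocyte-like cells 1.07% and 1.18%, and among non-epithelial cells 2.04% and 2.26%. The background, read in the cluster led by Slc16a3 and Cryab, was 0.29% and 0.48%, with median depths of 120 and 59 before thinning.

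Sebocyte-like and upper hair follicle-like cells were larger shares of the Utx-cKO epithelium. Because genes that define these classes differed at least 1.5-fold within them, shares come from a clustering without the 69 genes that differed that much in epithelial cells. Sebocyte-like cells were 8.42% (7.97 to 8.88) of WT and 12.9% (12.4 to 13.4) of Utx-cKO epithelial cells. Strips ranged from 5.57% to 11.1% and from 8.97% to 16.6%, so they overlapped. Upper hair follicle-like cells were 7.08% (6.67 to 7.50) and 10.9% (10.4 to 11.3), with strips from 5.78% to 8.48% and from 6.79% to 12.9%. Suprabasal keratinocyte-like cells were 21.9% (21.2 to 22.6) and 12.7% (12.3 to 13.2), with strips from 18.4% to 24.5% and from 10.1% to 16.5%. Their leading genes include Tgm3, Krt1 and Krt77 but also the basal marker Itga6. Most of these leading genes also lead the cluster named basal keratinocyte-like on all genes, so the class mixes layers. Granular keratinocyte-like cells were 14.5% and 15.1%, with overlapping strips. Epithelial cells made up 44.2% and 50.9% of all cells. Clustered on all panel genes, the sebocyte-like shares were 5.15% and 9.07%, with strips from 4.40% to 6.06% and from 7.91% to 10.1%. The basal or suprabasal ratio rests on the grouping: Utx-cKO over WT was 0.58, but 0.88 at a Leiden resolution of 0.5.

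**Figure D4:**
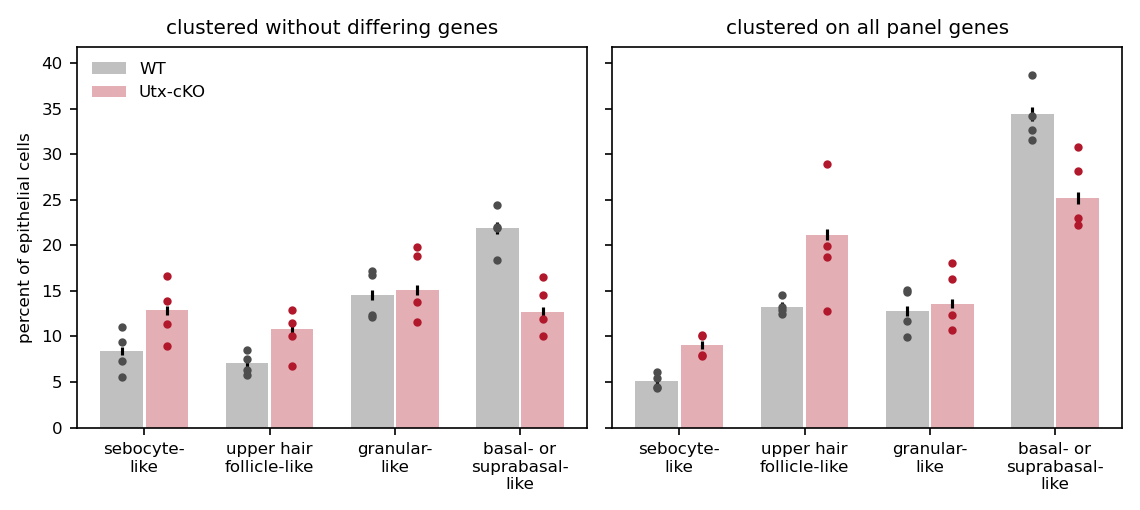
Percent of epithelial cells in each class, WT and Utx-cKO, for a clustering without the differing genes (left; its last class is suprabasal keratinocyte-like) and on all panel genes (right; its last class is basal keratinocyte-like). Bars are sections with exact 95% intervals and points are the 4 strips of each; sebocyte-like cells are 8.42% and 12.9% on the left.

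Within classes, several genes named for the whole epithelium recurred. Basal keratinocyte-like cells, a cluster that mixes basal with suprabasal genes, had higher Krt16 (log2 ratio 1.97, 1.43 to 2.55, from 38 and 108 counts), Gsdmc (1.73), Akr1c18 (1.46) and Sprr2a2 (1.44). They had lower Igfbp3 (-1.28), Prf1 (-1.17), Cd3g (-1.04) and the beta-defensin Defb1 (-1.01). Akr1c18 was 0.54 and Gsdmc 0.98 at a Leiden resolution of 2, and Krt16 was 2.70 in cells of at least 40 transcripts. Upper hair follicle-like cells had higher Elf3 (2.57, 1.85 to 3.38, from 17 and 169 counts), Rgs4 (2.32), Sprr2a2 (2.05) and Sprr2a3 (2.05). Elf3 had 1.88 in cells of at least 40 transcripts and Sprr2a3 1.42 over the nucleus alone, while Sprr2a2 had 2.67 and Sprr2a3 2.73 when clustered without the differing genes. They had lower Hrnr (-1.74, -1.96 to -1.53), Mfap4 (-1.23), Cd3g (-1.12) and Slc5a8 (-1.11).

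Granular keratinocyte-like cells had higher Gsdmc (2.07, 1.64 to 2.52) and Ndufa4l2 (1.15, 0.97 to 1.33), and lower Igfbp3 (-1.70, -1.99 to -1.43) and Rgcc (-0.95, -1.54 to -0.38). Counted over the nucleus alone, Gsdmc had 1.46, Igfbp3 -0.54, under 1.5-fold, and Rgcc -1.96. Another 4 genes of that class changed sign with these counts. Postn went from 1.37 to -1.13, Mmp2 from 1.25 to -0.70, Rbp2 from -1.18 to 0.84 and Dbi from -1.05 to 0.04. Sebocyte-like cells had higher Cd274 (0.89, 0.53 to 1.27) and Cd1d1 (1.01, 0.31 to 1.77, from 21 and 87 counts; 0.21 after thinning). They had lower Fn1 (-2.17), Liph (-1.98), Htra1 (-1.41) and Psat1, an enzyme of serine synthesis (-1.37, -1.56 to -1.18). Htra1 had -0.78 over the nucleus alone. With transcripts of quality 30 or more, Fn1 had -0.73 and Liph -0.85. Ptgr1 (0.82) and Elovl7 (0.76) changed sign at that quality, to -0.01 and -0.21.

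Genes with higher counts in non-epithelial cells of the Utx-cKO section included Il17a, Ctla4 and Tnc. Il17a, a cytokine of T cells, was 2.18 times higher (log2 ratio 1.13, 0.91 to 1.35), Ctla4, an inhibitory T cell receptor, 2.04 times (1.03, 0.73 to 1.34) and the matrix protein Tnc 2.09 times (1.06, 0.89 to 1.24). The transcription factor Tfap2a was higher too (1.32, 1.05 to 1.60, and 0.68 after thinning), as was the epidermal keratin Krt1 (2.05 times), at the low level of 72.5 and 149 CPM, from 97 and 141 counts. For comparison, the 20 negative control probes together had 331 and 561 transcripts in cells of all kinds. Gene transcripts in cells numbered 2645045 and 2442196, so this background was also higher in Utx-cKO on the CPM scale. How much of the counts of Il17a, Ctla4, Tfap2a and Krt1 is background was not measured. Strips of the sections were apart for Krt1 and overlapped for the others, and with mean counts per cell Tnc (0.57), Krt1 (0.54) and Ctla4 (0.54) were under 1.5-fold. Lower were Rgcc (1.99 times), the decoy receptor Il1r2 (1.91 times) and the desaturase Scd1 (1.83 times, -0.87, -0.91 to -0.84). The cluster led by Cd1d1 and Fasn, in which Scd1 is among the 10 leading genes, was 8.55% of WT and 4.04% of Utx-cKO cells. Its strips overlapped, from 6.38% to 12.8% and from 1.02% to 8.88%. Pla2g2d (-1.26) and Ptgs2 (-1.04) also met the size rule. Each came from 1 strip: Pla2g2d was 0.41 without WT strip 1, and Ptgs2 was 0.92 without WT strip 3. Il1r2 was -0.44 without that strip, under 1.5-fold.

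Of 450 genes compared in non-epithelial cells, 102 were at least 1.5 times higher in Utx-cKO and 9 lower. After centring on the median (0.22) these were 38 and 16, with mean counts per cell 3 and 71, and without WT strip 1 53 genes were higher. All Utx-cKO strips lay above all WT strips for 7 genes and below for 0, 1.56% of genes. Negative control probes were also higher in Utx-cKO relative to the gene transcripts in cells. How far background adds to the number of higher genes was not tested. Mast cell markers had 3 of 3 members higher (median 0.82, percentile 99.0), upper hair follicle genes 4 of 6 (0.81, 99.4) and hair matrix genes 2 of 3 (0.93, 98.3). Follicle genes were not alone in this: 7 of 11 wound and stress genes (0.65, 72.4), 7 of 14 granular and cornified layer genes (0.60, 68.0) and 4 of 12 suprabasal genes (0.46, 82.2) were higher, with 0 lower in each list. Epithelial cells were 44.2% of WT and 50.9% of Utx-cKO cells, clustered without the differing genes. Whether transcripts of neighbouring epithelial cells were assigned to non-epithelial cells was not tested, for these lists or for Krt1. The hair matrix median was 0.28 without Utx-cKO strip 3. The single dermal papilla marker measured, Sostdc1, had 0.94 (percentile 97.2). T and NK markers had 2 of 5 higher (0.30, 31.0). Medians of the other lists lay between -0.07 and 0.50, at percentiles from 13.8 to 96.1. That of cell cycle genes (0.15) was 0.79 without WT strip 3.

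Over whole sections, which need no clusters, Gsdmc (log2 ratio 1.85), Akr1c18 (1.60), Elovl6 (1.49), Cidea (1.47) and Sprr2a2 (1.27) had the highest ratios under the same rule. The lowest were those of Pla2g2d (-1.36), Il1r2 (-0.94), Tgm3 (-0.87), Cryab (-0.86) and Rgcc (-0.82). Strips of the sections were apart for Elovl6, Cidea and Rgcc. Without WT strip 1 Pla2g2d was 0.27, and without WT strip 3 Tgm3 was 0.79 and Il1r2 -0.50. Cryab was -0.43 after thinning and -0.54 without WT strip 4. Of 471 genes, 71 were at least 1.5 times higher and 12 lower. The split was 46 and 20 after centring on the median (0.10) and 18 and 75 with mean counts per cell. Without WT strip 1, 40 genes were higher. Lower genes numbered 22 without WT strip 3 and 30 without Utx-cKO strip 3.

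The median nucleus area of epithelial cells was 19.0 µm² in WT and 19.5 µm² in Utx-cKO, a difference that changed sign (-0.18) without WT strip 3. The median distance of granular keratinocyte-like cells to the nearest basal keratinocyte-like cell was 8.34 and 8.59 µm. Because the latter cluster mixes basal with suprabasal genes, this is no distance to the basal layer. That difference also changed sign, to -0.98 µm in cells of at least 40 transcripts and -0.21 µm at a Leiden resolution of 2. Of cells in the cluster led by C1qa and Cd68, genes of macrophages, 46.9% and 51.5% lay within 50 µm of an epithelial cell. The difference in this share was -10.9 percentage points without WT strip 1, -0.20 without Utx-cKO strip 3 and 16.3 when clustered without the differing genes.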

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

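All explanations in this part, and the values used to test them, were chosen after the results were seen, though thinning, equal cluster shares and clustering without the differing genes were alternatives fixed beforehand. The Utx-cKO section held 14913 segmented cells under 20 transcripts (28.5% of its cells), against 7108 (17.6%) in the WT section. These cells are left out of the main comparisons and enter only alternatives. The 2 highest negative control probes, also outside every comparison, had 199 and 197 transcripts in Utx-cKO cells and 117 and 116 in WT cells. Each stands here because a signal outside the main measurement was above its level in the control section.

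Kdm6a counts remained in epithelial cells where the labels give a deletion, with log2 ratios from 0.08 in granular keratinocyte-like cells to -0.86 in 1 unnamed cluster. If transcripts of neighbouring non-epithelial cells had been assigned to epithelial cells, other non-epithelial transcripts would reach them in the same proportion. The median of 33 non-epithelial markers in Utx-cKO epithelial cells was 18.5% of its non-epithelial level, against 85.7% for Kdm6a, although 6 of the 33 reached that level. In each of the 9 epithelial clusters the median, between 8.83% and 32.05%, was below the level of Kdm6a, between 49.9% and 122%, which argues against neighbouring cells as the main source. The 122% is from the unnamed cluster led by Dct and Pmel, markers of melanocytes, a non-epithelial class. Basal keratinocyte-like cells had 121%. Probes outside the deleted part of the gene cannot be told apart from incomplete deletion, neither by the pooled log2 ratio of -0.32 nor by the spread among clusters, since probe positions are not given in the sources used here.

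Cd3e and Cd3g were lower in the Utx-cKO epithelium. Lower depth of the cells kept is argued against, since after thinning each cell to the same depth 1.85% of Utx-cKO epithelial cells still held a Cd3 transcript against 2.99% in WT. Thinning cannot speak for T cells under 20 transcripts, because such cells were left out before it. A different mix of clusters is also argued against, since with equal cluster shares the median log2 ratio of both genes was -0.84. Loss of T cells to other clusters is argued against as the sole source, since the whole-section median, which needs no clusters, was -0.46. It is not excluded as a part. The whole-section ratio was smaller than the epithelial ones, and thinned non-epithelial shares were 2.04% in WT and 2.26% in Utx-cKO. Cells under 20 transcripts are left out of this median too. Fewer T cells of every kind cannot be told apart from lower Cd3e and Cd3g in the T cells present: the other 3 measured T cell markers had a median of -0.12 but went both ways (Cd3d -0.23, Thy1 -0.12, Cd8a 0.52), and Prf1 had -0.74.

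Sebocyte-like cells were a larger share of the Utx-cKO epithelium. Genes at least 1.5 times apart are argued against as the sole source, since the ratio of shares was 1.53, with a lower bound of 1.40, without them. Smaller differences are not excluded. Of the 10 measured members of the lipid list, 3 were under 1.5-fold and stayed in the clustering, and the lowest log2 ratio was 0.36. More follicles or glands per length of section cannot be told apart from more sebocyte-like cells in each. Clustered on all genes, cells of the cluster led by Lhx2 and Tbx1 had a ratio per mm of 1.03. In that clustering groups of sebocyte-like cells had 1.78 and sebocyte-like cells 2.43. Clustered without the differing genes, upper hair follicle-like cells had 2.14, groups of sebocyte-like cells 1.48 and sebocyte-like cells 2.13. Skin site, plane of section and animal cannot be told apart from genotype, and the lowest Utx-cKO strip, at 8.97%, lay below the highest WT strip, at 11.1%.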

How the results depend on the processing

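Leaving out strips and clustering on all genes were alternatives chosen after the data were seen, and all others were fixed beforehand. Of the values of counts, shares and geometry, 111 were the same and 47 moved under alternatives fixed beforehand. A change of sign counts as reversed only where the main value was past its size rule or had an interval without 0, so the distance, whose sign changed, counts as moved. Under added ones 89 were the same, 42 moved and 3 reversed. For list medians these numbers were 431, 95 and 1, then 226, 45 and 1. For named genes they were 573, 280 and 11, then 205, 150 and 5. Counting intervals are narrow at this depth, so small moves are counted. No paired analysis was possible because the labels pair no WT sample with a Utx-cKO sample. Except for the scale of counts, the cause was not tested for any of the moves. Depth limits which genes are compared within classes, since a gene needs 100 counts there.

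Numbers of genes past 1.5-fold moved most with the scale. With mean counts per cell, which are lower in the Utx-cKO section, higher and lower genes were 25 and 53 in epithelial cells, 3 and 71 in non-epithelial cells and 18 and 75 in whole sections. Centred on the median, lower epithelial genes were 30, non-epithelial genes 38 and 16, and whole-section genes 46 and 20. Higher non-epithelial genes were 59 at quality 30, 66 over nuclei alone, 46 on the right sides and 30 after thinning. Thinning also gave 26 higher epithelial and 6 lower whole-section genes. Lower whole-section genes were 19 with at least 40 transcripts per cell and 20 on the left sides. With cells called by their markers, lower genes were 29 in epithelial and 3 in non-epithelial cells. With all decoded transcripts 116 whole-section genes were higher.

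The Kdm6a log2 ratio was -0.13 over nuclei alone, -0.57 with mean counts per cell, -0.44 when centred and -0.40 without the 10 most abundant genes. In granular keratinocyte-like cells, counts over nuclei alone reversed Postn (-1.13), Mmp2 (-0.70), Rbp2 (0.84) and Dbi (0.042). In sebocyte-like cells Ptgr1 reversed at quality 30 (-0.007) and after thinning (-0.079). Elovl7 reversed there at quality 30 (-0.21), over nuclei alone (-0.29), with at least 10 transcripts per cell (-0.12), at resolution 0.5 (-0.11) and without the differing genes (-0.10). The granular and cornified list reversed with cells called by their markers (0.073).

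The share ratio of sebocyte-like cells was 1.78 at quality 30, 1.73 over nuclei alone, 1.83 with at least 40 transcripts, 1.69 at resolutions of 0.5 and 2, and 1.76 on all genes. That of basal- or suprabasal-like cells was 0.71, 0.78 and 0.68 under the first 3 of these, 0.72 with at least 10 transcripts, 0.88 and 0.66 at these resolutions and 0.73 on all genes. The upper hair follicle-like ratio was 1.15 at resolution 2, the granular-like ratio 1.13 with at least 40 transcripts, and the epithelial ratio 1.11 and 1.22 with at least 10 and 40. With at least 40 transcripts the difference in nucleus area was 0.90 µm² and that in distance -0.98 µm. The distance difference was -0.21 at resolution 2 and 0.46 on the left sides. The difference in C1qa-led cells near epithelium was 11 points with at least 40 transcripts and 16.3 without the differing genes. No cluster gave an upper hair follicle-like share at quality 30 or resolution 0.5, nor a distance at resolution 0.5 or without the differing genes.

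With each strip left out in turn, higher genes ranged from 53 to 139 in non-epithelial cells and from 40 to 101 in whole sections. Lower genes ranged from 13 to 33 in epithelial cells, 5 to 11 in non-epithelial cells and 11 to 30 in whole sections. Kdm6a ranged from -0.53 to -0.066. Share ratios ranged from 1.06 to 1.23 for epithelial, 1.31 to 1.77 for sebocyte-like, 0.97 to 1.16 for granular-like and 0.54 to 0.63 for basal- or suprabasal-like cells. The ratio of sebocyte-like cells per mm, 2.13, ranged from 1.66 to 2.78 and was 2.43 on all genes. Nucleus area ranged from -0.18 to 1.58 µm² and C1qa-led cells near epithelium from -10.9 to 8.67 points, with -0.20 without Utx-cKO strip 3. Pla2g2d ranged from -1.85 to 0.41 in non-epithelial cells and from -1.95 to 0.27 in whole sections, Tgm3 from -2.10 to 0.64 in epithelial cells and from -1.34 to 0.79 in whole sections, and Ptgs2 from -1.68 to 0.92. The granular and cornified list ranged from -0.39 to 0.031.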

Other observations

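No test was run in this part, and its values were chosen after the results were seen. With 30.0 mm of WT and 28.0 mm of Utx-cKO tissue, sebocyte-like cells numbered 41.2 and 87.6 per mm when clustered without the differing genes. Their strips ranged from 27.2 to 76.8 and from 64.2 to 144, so they overlapped. Groups of at least 3 such cells numbered 4.46 and 6.58 per mm and held 8.89 and 12.97 cells on average. Upper hair follicle-like cells numbered 34.6 and 73.9 per mm and granular keratinocyte-like cells 71.1 and 103. Clustered on all genes, sebocyte-like cells numbered 24.99 and 60.8 per mm, basal keratinocyte-like cells 167 and 169, and cells of the cluster led by Lhx2 and Tbx1 77.5 and 79.7.

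Outside the epithelium, the cluster led by Kit and Gata2, genes of mast cells, was 0.88% of WT and 1.78% of Utx-cKO cells, with strips from 0.72% to 1.18% and from 1.203% to 2.63%. Its cells had a median of 25 transcripts, close to the minimum of 20. It also carried Stfa2 and Chil4, which are expressed by granulocytes. Its leading genes Gata2 and Serpinb1a were at least 1.5 times apart within it. Clustering without the differing genes gave no cluster led by Kit and Gata2. Both were then among the leading genes of a cluster of 6.03% of WT and 6.87% of Utx-cKO cells. The higher share thus rests on the clustering on all genes. The cluster led by Mfap4 and Igfbp2, with the fibroblast genes Lum and Pdgfra, was 10.8% and 7.46%. Its strips overlapped, from 8.19% to 13.7% and from 5.17% to 9.65%. That led by Igfbp3 and Mmp27 was 3.79% and 5.55%. Its strips overlapped widely, from 1.21% to 7.85% and from 1.25% to 10.5%, and strip 3 was highest in each section. The cluster led by C1qa was 9.47% and 9.66%, with WT strips from 4.35% to 19.2%. The wound and stress list was also higher within epithelial classes: 4 of 6 members in basal keratinocyte-like cells (median log2 ratio 0.67) and 2 of 3 in upper hair follicle-like cells (1.36). Leading genes of each cluster were left out, among them Krt17 in upper hair follicle-like cells.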
